A study of Homo sapiens with 40 samples.

How the data were processed

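The deposited values were probe set signals in intensity units on a linear scale, which were made with MAS5, per the submitters' processing notes. The rule by which arrays were scaled to each other was not given in the sources used here. The 2% trimmed means of the arrays differed 3.05-fold between the highest and the lowest, so the arrays had not been scaled to 1 common trimmed mean. The slope of each array's regression on the mean array ran from 0.9565 to 1.046, so by that measure the arrays were on nearly the same scale. The deposited scale was kept, values under the 20th percentile of the table (a signal of 126) were set to that floor, and signals were put on a log2 scale. A difference is a lower bound where values at the floor are found only in the group with the lower mean. With values at the floor in both groups it is no bound.

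Probe sets were assigned to genes by the GEO platform annotation. Of the 22283 probe sets, 68 were controls, and 52 probe sets of sex-linked genes (XIST and Y-linked genes) were left out. Among the rest, 19065 carried 1 gene symbol, 1043 carried several and 2107 carried none. Probe sets with several symbols or none were tested and are not named. A probe set was tested if its signal was over the median of the table (546) in at least 6 arrays, the size of the smallest group. This filter left 14199 probe sets and 8555 genes. Each gene was represented by its probe set with the highest mean signal.

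Groups were compared with limma 3.58.1 in R 4.3.3, in 1 linear model for the 3 groups with moderated variances and an intensity trend. P-values were two-sided and were adjusted by the Benjamini-Hochberg method over all probe sets tested. A gene was called at an adjusted p under 0.05. Errors of fold changes are standard errors from that model. No batch, age or pairing was given in the labels, so the model had no covariate.

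The gene lists were immunoglobulin genes, plasma cell, B cell, T cell, cytotoxic cell, macrophage, dendritic cell, neutrophil and mast cell, MHC class I, MHC class II, type I interferon, interferon gamma and chemokine, B cell survival, complement, myofibre, fast fibre, slow fibre, regeneration, oxidative phosphorylation, fatty acid oxidation, glycolysis, proteins described in IBM fibres, endoplasmic reticulum stress, lysosome and autophagy, extracellular matrix, endothelial, adipocyte, erythrocyte, nerve and Schwann cell, keratinocyte, immediate early, metallothionein, ribosomal and cell cycle genes. The 34 lists, the tests, the thresholds, the alternatives listed first below and the rule for named genes were fixed before the data were examined. Several lists share members, such as CASQ1 in the myofibre and fast fibre lists and CTSS in the macrophage and MHC class II lists. Each list with at least 3 tested members was compared with all other genes by camera, with a preset correlation between genes of 0.01, and the test was repeated with an estimated correlation. Fry, the rotation test of limma, asked whether the members of a list moved one way on balance, without a comparison with other genes. Both were adjusted over the 33 lists tested. A list score was the mean over the tested members of the log2 signal, centred on each gene's mean over the 40 arrays. Scores were compared by two-sided permutation tests of the difference in means, exact where a group had fewer than 10 arrays and with 100000 resamples otherwise, adjusted over the lists. Correlations across the IBM arrays were given as Pearson's r and Spearman's rho, with permutation p-values adjusted over the 10 scores compared.

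The rule for named genes took, against NORM, the 5 called genes with the highest and the 5 with the lowest fold change. It also took all tested plasma cell and B cell genes, the 3 immunoglobulin genes with the smallest p, and the 2 genes with the smallest p of 11 further lists. For IBM against PM, it took the 5 genes with the smallest p in each direction and 1 gene of each of those lists. Of every other list that passed camera it took the 1 gene with the smallest p. A gene named in 1 comparison could be named in another.

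Alternatives were quantile normalization, subtraction of each array's median, floors at the 5th and 40th percentile, no filter, a filter at the 75th percentile, the mean of a gene's probe sets, a fit of only the 2 groups compared, no intensity trend, array weights, the GAPDH 3' to 5' ratio as a covariate, and omission of each array in turn. Those chosen after seeing the data were the omission of arrays with a low scale or with a GAPDH 3' to 5' ratio over 3, each also with quantile normalization, a block for low-scaled arrays, a fit of the low-scaled arrays alone, and an estimated correlation for list calls gained in another setting or with 1 array left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.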

Results

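Transcript signal was measured with a microarray of 22283 probe sets in 40 samples of human muscle, with total RNA on 1 array for each sample. The labels placed 23 samples in a group named IBM, 6 in PM and 11 in NORM. From the title of the series, IBM is inclusion body myositis and PM is polymyositis, which are inflammatory diseases of muscle, and NORM was taken as the control group. The title names plasma cells, the antibody-secreting descendants of B cells, so the comparisons ask how their transcripts and those of other infiltrating cells differ between groups. Replicates are separate samples of a group, and the labels gave no batch, date or pairing.

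Signals ran from 0 to 254228. The median signal of an array was 291 to 1191 in IBM, 292 to 799 in PM and 281 to 656 in NORM. In 7 arrays (3 IBM, 1 PM and 3 NORM) the 2% trimmed mean was at most 979, against at least 1231 in the other arrays. These are called low-scaled arrays. The name refers to the trimmed mean only, since their slopes on the mean array were not low (0.9952 to 1.046). The ratio of 3' to 5' signal of GAPDH, a measure of RNA integrity, was over 3 in 3 IBM arrays, 1 PM array and 0 NORM arrays, with highest values of 11.89, 6.603 and 1.212. The PM array concerned, replicate 6, was also low-scaled. The number of arrays limits the precision of each comparison. In simulated data with the spread of each probe set, limma recovered 73.1% of genes changed 2-fold and 22.4% of genes changed 1.5-fold for IBM against NORM. For PM against NORM it recovered 28.4% and 7.46%, and for IBM against PM 46.3% and 10.4%. Each simulation was a single draw with independent normal noise and 66 or 67 changed genes at each fold. The adjustment for multiple tests is less strict where more genes change, so these rates are only a rough guide to the real comparisons.

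The comparison of IBM with NORM asks what differs in IBM muscle. Immunoglobulin transcripts were among those with the largest fold changes. IGLV1-44, a light chain variable gene, was 51.2-fold higher in IBM (log2 fold change 5.68 ± 0.58 SE, n = 23 and 11) and above every NORM array in 23 of 23 IBM arrays. IGLC1 and IGKC, light chain constant genes, rose 30.1-fold (4.91 ± 0.59) and 25.3-fold (4.66 ± 0.62). IGHM, the heavy chain of IgM, rose 24.7-fold (4.62 ± 0.65). PSMB8, an immunoproteasome subunit, was at the floor in all 11 NORM arrays and 1 IBM array, and against that floor it was 26.5-fold higher in IBM, above every NORM array in 22 of 23. MYH3, the embryonic myosin heavy chain, rose 24.4-fold (4.61 ± 0.45).

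Of the 11 immunoglobulin genes tested, 9 were called higher and 0 lower (11 higher, adjusted over the list alone). Their median log2 fold change of 1.84 lay 1.62 above that of all genes. Camera gave an adjusted p of 1.37e-08, but adjusted p = 0.149 with an estimated correlation. Counting also the probe sets that carry several immunoglobulin symbols, 44 of 53 immunoglobulin probe sets were called higher in IBM. The list score was 2.82 higher in IBM (permutation test, adjusted p = 3.67e-05) and above every NORM array in 21 of 23 IBM arrays.

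Of the 14 plasma cell genes tested, 10 were called higher and 0 lower (11 higher, adjusted over the list alone). JCHAIN, which joins immunoglobulin units into polymers, rose 21.5-fold (4.42 ± 0.59) and was above every NORM array in 22 of 23 IBM arrays. FKBP11, a chaperone of secretory cells, rose 7.79-fold (2.96 ± 0.34) and was also above every NORM array in 22. PIM2 rose 3.81-fold (1.93 ± 0.30), POU2AF1, a transcriptional coactivator of B lineage cells, 3.39-fold (1.76 ± 0.36) and SEL1L3 3.13-fold (1.65 ± 0.34). CD27, SDC1, IRF4, SSR4 and XBP1 rose 1.85-fold to 2.13-fold. ITM2C (1.11 ± 0.45), SLAMF7 (0.48 ± 0.38), CD38 (−0.25 ± 0.23) and TENT5C (−0.35 ± 0.23) were not called. With quantile normalization CD27 was not called (adjusted p = 0.0561) and TENT5C was called lower (−0.64 ± 0.18). Camera gave an adjusted p of 0.000114 for the list, but adjusted p = 0.261 with an estimated correlation. The score was 1.34 higher in IBM (permutation test, adjusted p = 9.9e-05), above every NORM array in 21 of 23 IBM arrays. Within the low-scaled arrays (3 IBM and 3 NORM) the list median was 0.28 and its call was lost. Only 4449 genes passed the signal filter there, against 8555 with all arrays. With so few arrays, genes dim in NORM could be removed before the test. The lost call therefore cannot decide whether plasma cell genes rose in the low-scaled arrays.

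Of the 6 B cell genes tested, 2 were called higher and 0 lower (3 higher, adjusted over the list alone). CD79A, a chain of the B cell receptor complex, rose 2.34-fold (1.23 ± 0.25) and CD22, a B cell surface receptor, 1.72-fold (0.78 ± 0.27). With quantile normalization CD22 was not called (0.47 ± 0.24, adjusted p = 0.138). MS4A1, which encodes CD20, had a log2 fold change of 0.69 ± 0.29 that was not called (adjusted p = 0.0933). TCL1A (0.22 ± 0.32), BLK (0.20 ± 0.23) and TNFRSF13B (−0.09 ± 0.26) were not called either. The list was not called by camera (adjusted p = 0.423), while fry gave an adjusted p of 0.0165. The score was 0.51 higher in IBM (permutation test, adjusted p = 0.0153) and above every NORM array in 10 of 23 IBM arrays. With quantile normalization it was 0.245 higher (permutation test, adjusted p = 0.0479).

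**Figure D1:**
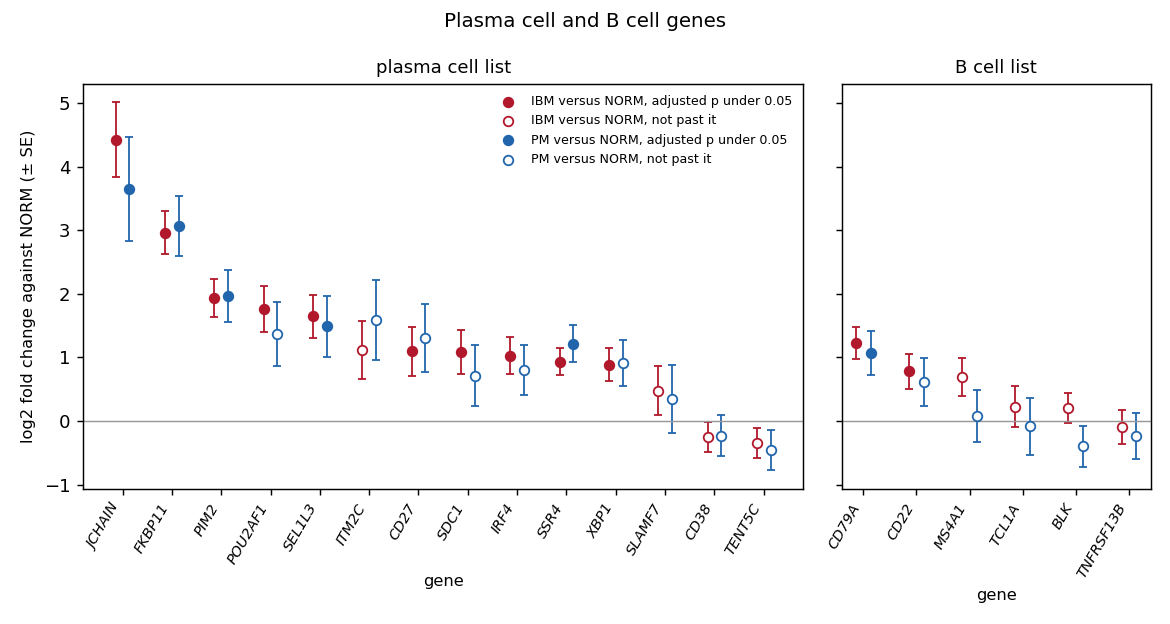
Log2 fold change against NORM (vertical axis) of the tested plasma cell and B cell genes (horizontal axis) in IBM (n = 23) and PM (n = 6), against 11 NORM arrays; points are fold changes, bars are ± 1 SE, and filled points passed an adjusted p under 0.05. JCHAIN stands highest in both diseases (4.42 and 3.65), and among B cell genes CD79A is called in both (1.23 and 1.07).

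Genes of T cells, cytotoxic cells and macrophages were called higher as well. Of 12 T cell genes 10 rose, with CD4 5.75-fold higher (2.52 ± 0.41) and TRBC1, a T cell receptor chain, 4.49-fold higher (2.17 ± 0.35). Of 14 cytotoxic genes 10 rose, with CD8A 5.6-fold higher (2.48 ± 0.35) and GZMK, a granzyme, 5.06-fold higher (2.34 ± 0.34). All 18 macrophage genes tested rose, with LYZ, lysozyme, 12.9-fold higher (3.69 ± 0.46) and CD163, a scavenger receptor, 6.14-fold higher (2.62 ± 0.29). Camera gave adjusted p-values of 1.67e-06, 4.53e-06 and 4.13e-17. The calls were lost with adjusted p = 0.212, adjusted p = 0.224 and adjusted p = 0.102 with an estimated correlation. The 3 scores were above every NORM array in 21, 20 and 22 of 23 IBM arrays.

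Genes of antigen presentation rose with them. Of 15 MHC class I genes 13 were called higher, with HLA-B (4.70-fold, 2.23 ± 0.16, 23 of 23 arrays above every NORM array) and HLA-C (4.42-fold, 2.14 ± 0.20). Of 13 MHC class II genes 12 were called higher, with HLA-DPB1 (7.20-fold, 2.85 ± 0.37) and CD74, the invariant chain (5.47-fold, 2.45 ± 0.30). The camera test had adjusted p-values of 1.55e-16 and 3.65e-11, with adjusted p = 0.102 for both lists with an estimated correlation. Of 23 type I interferon genes 16 rose, with ISG15 (4.97-fold, 2.31 ± 0.31) and IFIT3 (3.88-fold, 1.96 ± 0.30), both induced by interferon. Camera gave adjusted p = 3.28e-08, and adjusted p = 0.224 with an estimated correlation. Of 16 interferon gamma and chemokine genes 14 rose, with CCL2, a monocyte chemokine (6.58-fold, 2.72 ± 0.35), and GBP2 (5.29-fold, 2.40 ± 0.28). The camera test had adjusted p = 2.38e-13, and adjusted p = 0.102 with an estimated correlation. Of 15 complement genes 12 rose, C1S by 4.26-fold (2.09 ± 0.24), with camera adjusted p = 2.98e-08 and adjusted p = 0.172 with an estimated correlation. Of 9 B cell survival genes 4 rose, with TNFSF13, the ligand APRIL, 4.66-fold higher (2.22 ± 0.36). Camera gave adjusted p = 0.048, and adjusted p = 0.516 with an estimated correlation.

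**Figure D2:**
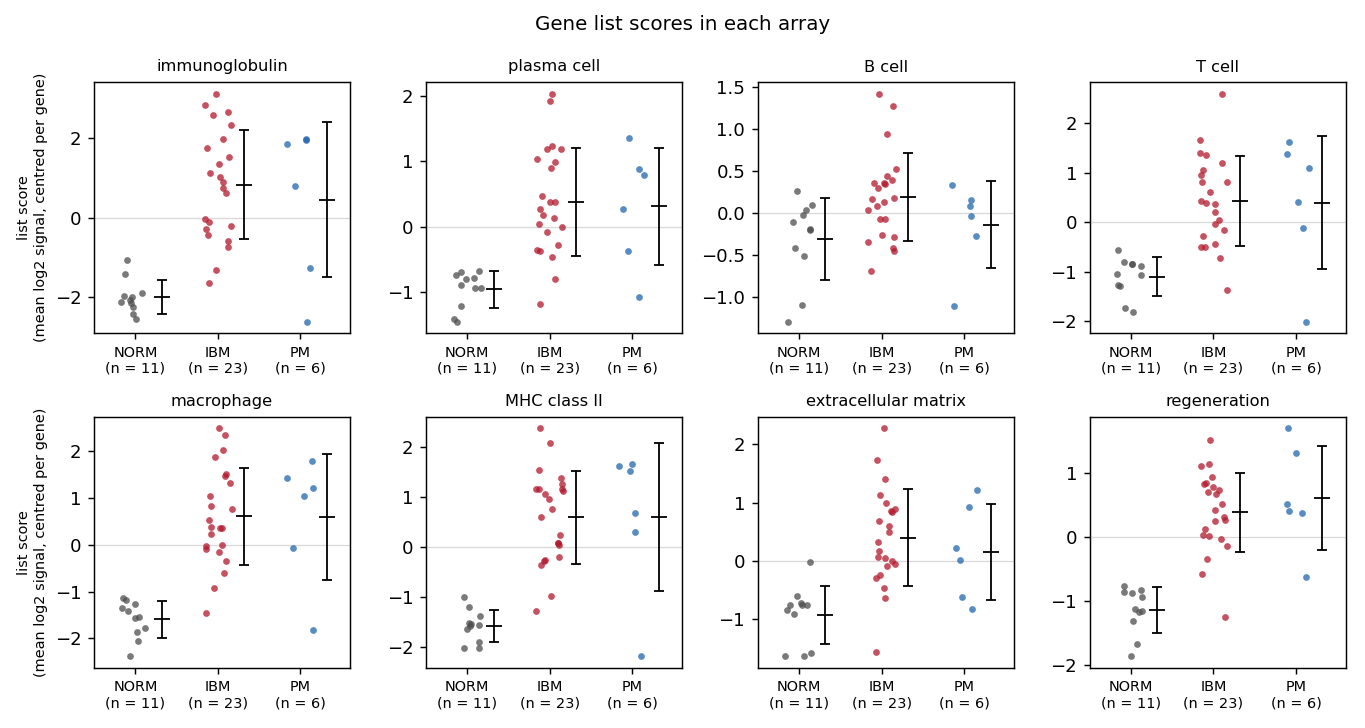
List scores (vertical axis, mean log2 signal centred per gene) of 8 gene lists in each array of NORM (n = 11), IBM (n = 23) and PM (n = 6) on the horizontal axis; points are arrays, and the line and bar are the mean ± 1 SD. The immunoglobulin score was above every NORM array in 21 of 23 IBM arrays and 4 of 6 PM arrays, and the B cell score in 10 of 23 and 1 of 6.

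Muscle genes moved in both directions. Of 13 regeneration genes 7 were called higher and 0 lower, with GADD45A, a stress-induced gene raised in denervated muscle, 6.83-fold higher (2.77 ± 0.29) beside MYH3. The camera test had adjusted p = 3.74e-06, and adjusted p = 0.149 with an estimated correlation. Of 29 myofibre genes 7 were called lower and 1 higher (11 lower and 1 higher, adjusted over the list alone). RYR1, the calcium release channel, was 1.35-fold lower (−0.44 ± 0.14), while PVALB, a calcium buffer, was 5.11-fold higher (2.35 ± 0.50). The myofibre median of −0.26 differed by −0.49 from that of all genes (camera adjusted p = 4.29e-13), and this was the 1 list of this comparison whose call held with an estimated correlation (adjusted p = 0.0385). The score differed by −0.22 from NORM (permutation test, adjusted p = 0.0122), a call that was lost with quantile normalization (adjusted p = 0.0746).

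Of 11 fast fibre genes 2 fell and 1 rose (camera adjusted p = 9.78e-05, adjusted p = 0.194 with an estimated correlation). Of 9 slow fibre genes 4 fell and 1 rose, CASQ2, a calcium-binding protein (1.5-fold, 0.58 ± 0.18; within the 7 low-scaled arrays −0.20). Camera gave adjusted p = 1.85e-05 for the slow fibre list, and adjusted p = 0.102 with an estimated correlation. With quantile normalization neither fibre type list was called (adjusted p = 0.201 and 0.314). Of 16 glycolysis genes 4 fell and 0 rose, with ENO3, muscle enolase, 1.41-fold lower (−0.50 ± 0.14; camera adjusted p = 1.37e-08, adjusted p = 0.102 with an estimated correlation). Of 27 oxidative phosphorylation genes 1 fell, COX6A2, the muscle form of a cytochrome oxidase subunit, which was 1.45-fold lower (−0.54 ± 0.12). CYC1 had −0.30 ± 0.13 (adjusted p = 0.101). The list median was −0.13 (camera adjusted p = 5.15e-07, adjusted p = 0.275 with an estimated correlation), and 6 genes of this list were called lower with quantile normalization. Of 19 fatty acid oxidation genes 0 were called by limma. FABP3, a fatty acid binding protein, had the smallest p (−0.73 ± 0.29, adjusted p = 0.0728). The list median was −0.13 (camera adjusted p = 0.000109, adjusted p = 0.238 with an estimated correlation), and 7 genes were called lower with quantile normalization.

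Of 22 extracellular matrix genes 17 rose, with TIMP1, a metalloproteinase inhibitor, 4.81-fold higher (2.27 ± 0.23; camera adjusted p = 5.9e-10, adjusted p = 0.212 with an estimated correlation). Of 18 endoplasmic reticulum stress genes 8 rose, with PDIA4, a protein disulfide isomerase, 2.26-fold higher (1.18 ± 0.25; camera adjusted p = 0.0394, adjusted p = 0.62 with an estimated correlation). Of 8 metallothionein genes 5 rose, with MT2A, a metal-binding protein, 1.83-fold higher (0.87 ± 0.18; camera adjusted p = 0.036, adjusted p = 0.456 with an estimated correlation). With quantile normalization the metallothionein list was not called (adjusted p = 0.0636). Of 17 genes for proteins described in IBM fibres 6 rose, with CST3, cystatin C, 2.83-fold higher (1.5 ± 0.20) and GSN, gelsolin, 2.02-fold higher (1.01 ± 0.18). Another GSN probe set had the opposite sign. Camera did not call this list (adjusted p = 0.328). With quantile normalization camera called it higher (adjusted p = 0.0249), but not with an estimated correlation (adjusted p = 0.142). Of 20 ribosomal genes 1 rose, RPL3 (2.56-fold, 1.36 ± 0.20), and 1 fell. The ribosomal median was −0.06, its mean was 0.04, and camera called it lower than other genes (adjusted p = 0.00784, adjusted p = 0.456 with an estimated correlation, and 0.877 with quantile normalization).

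The other lists were not called by camera in IBM against NORM. Their median log2 fold changes were 0.66 for dendritic cell genes (3 of 8 higher), 0.62 for neutrophil and mast cell genes (3 of 8), 0.17 for lysosome and autophagy genes (4 of 17) and 0.51 for endothelial genes (5 of 14). They were 0.65 for adipocyte genes (1 of 9), 0.27 for keratinocyte genes (1 of 4), 0.73 for immediate early genes (5 of 13) and 0.50 for cell cycle genes (2 of 9). Of 3 erythrocyte genes 0 were called by limma, with a median of 0.09 that camera placed below other genes (adjusted p = 0.423). Nerve and Schwann cell genes were not tested, because 2 of 12 members passed the filter. The genes with the lowest fold changes were AQP4, the water channel of the fibre membrane (2.93-fold lower, −1.55 ± 0.29, below every NORM array in 21 of 23 IBM arrays), and LGR5 (2.88-fold lower, −1.52 ± 0.38). SLC47A1, SLC7A2, an amino acid transporter, and HIPK3 were 2.46-fold to 2.58-fold lower.

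In all, limma called 1795 of 8555 genes between IBM and NORM, 1660 higher and 135 lower. The median log2 fold change of all probe sets was 0.20, and with quantile normalization it was −0.06. That scaling gave 1431 genes higher and 1083 lower, so the share of higher calls went from 92.5% to 56.9%. Of the calls as deposited, 1377 higher and 125 lower genes were also called with quantile normalization, and 0 in the opposite direction. Among calls of at least 2-fold, 819 were higher and 14 lower as deposited, and 501 and 54 with quantile normalization. The GAPDH ratio over 3 in 3 IBM arrays moved with the group; without such arrays 1823 genes were called. Of the 579 called genes with several probe sets, 64 had another of opposite sign. Some calls near the threshold were lost with 1 array left out: CD27 with any of 17 arrays (0.97 to 1.11), CD22 with any of 9 (0.64 to 0.75), SLC7A2 with any of 13 (−1.28 to −1.18) and SDC1 without NORM replicate 9 (0.95). The camera call was lost for B cell survival genes with any of 21 arrays (0.76 to 0.93), for metallothionein genes with any of 6 (0.51 to 0.60) and for endoplasmic reticulum stress genes without NORM replicate 9 (0.42) or 10 (0.45). Other calls were gained: ITM2C with any of 5 arrays left out (1.20 to 1.30) and FABP3 with any of 4 (−0.85 to −0.79). Camera called dendritic cell (0.76) and cell cycle genes (0.58) without NORM replicate 2 and immediate early genes (0.86) without NORM replicate 7, but 0 of these 3 calls held with an estimated correlation (adjusted p = 0.495 to 0.496).

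**Figure D3:**
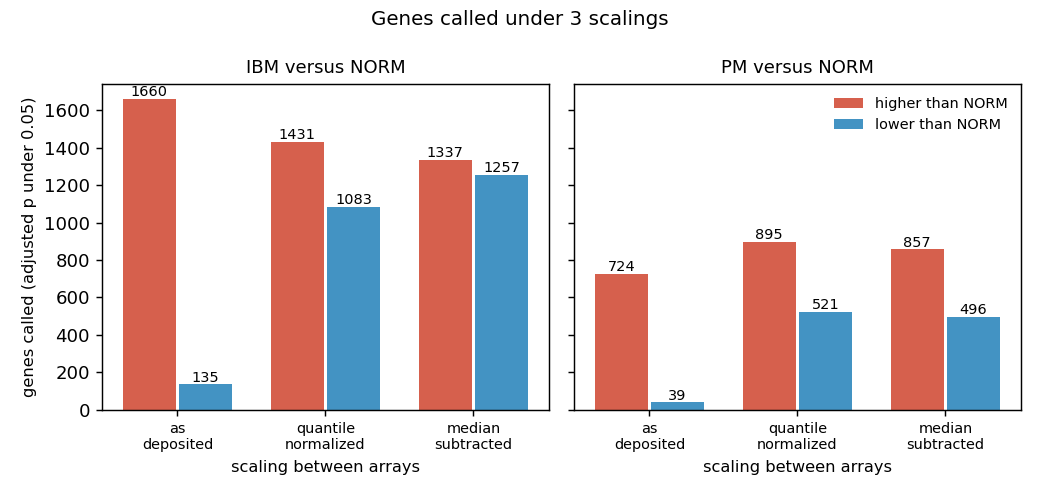
Number of genes called against NORM (vertical axis, adjusted p under 0.05) in IBM and in PM under 3 scalings between arrays (horizontal axis); bars are counts of genes higher or lower than NORM. In IBM the lower calls went from 135 as deposited to 1083 with quantile normalization and 1257 with the array median subtracted.

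Across the 23 IBM arrays, the immunoglobulin score was correlated most closely with the plasma cell score. Pearson's r was 0.902 and Spearman's rho 0.883 (permutation p = 1e-05 for each, the smallest possible with 100000 resamples; adjusted p = 1e-04), and r was 0.873 without the 2 arrays farthest from the median. With the B cell score r was 0.614 and rho 0.64 (permutation p = 0.00171 and 0.00132, adjusted p = 0.00244 and 0.00189), and r was 0.551 without those arrays. With quantile normalization the plasma cell r was 0.901 and the B cell r was 0.272 (permutation p = 0.208, adjusted p = 0.208). With quantile normalization and without the arrays with a GAPDH ratio over 3, the B cell r was 0.521 over 20 arrays (permutation p = 0.0188, adjusted p = 0.0376). This family held 10 scores, and all 10 passed an adjusted p of 0.05 as deposited.

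The T cell, cytotoxic, macrophage, MHC class II and type I interferon scores had r from 0.715 to 0.737 with the immunoglobulin score and rho from 0.672 to 0.726. Their permutation p-values ran from 6e-05 to 0.00013 for r and from 0.00014 to 0.00074 for rho, with adjusted p at most 0.000217 and 0.00123. Without the 2 farthest arrays their r was 0.624 to 0.741. The myofibre score had r = −0.489 and rho = −0.442 (permutation p = 0.0178 and 0.0364, adjusted p = 0.0178 and 0.0364), and r was −0.426 without those arrays. The regeneration score had r = 0.512 and rho = 0.456 (permutation p = 0.012 and 0.0297, adjusted p = 0.0133 and 0.033), and r was 0.438 without those arrays. With quantile normalization r was −0.408 for myofibre and 0.32 for regeneration (permutation p = 0.0525 and 0.135), so neither passed. The log2 GAPDH ratio was itself correlated with the immunoglobulin score (r = −0.504, rho = −0.617, permutation p = 0.0114 and 0.00193, adjusted p = 0.0133 and 0.00241; r = −0.324 without the 2 farthest arrays).

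**Figure D4:**
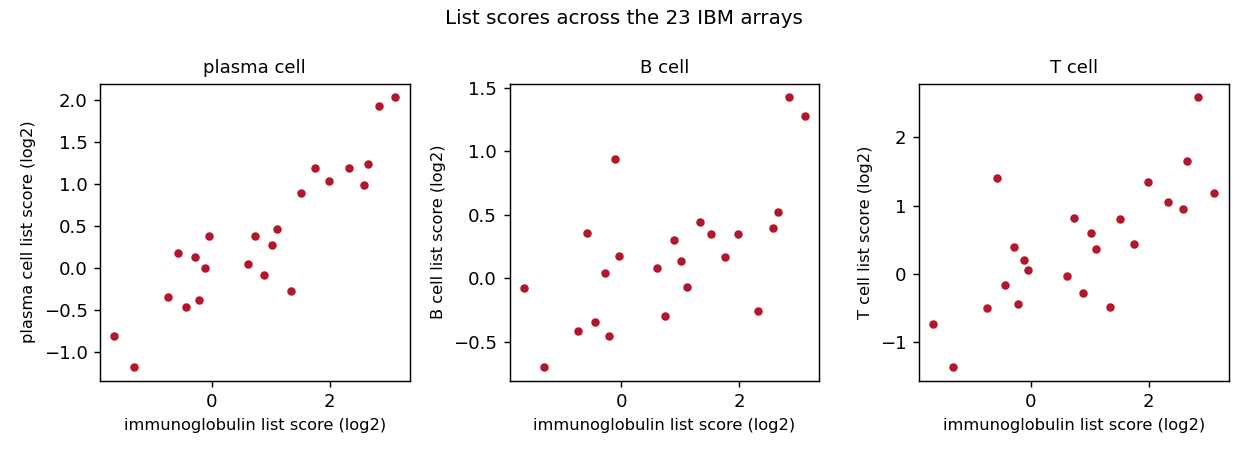
Plasma cell, B cell and T cell list scores (vertical axes, log2) against the immunoglobulin list score (horizontal axes, log2) in the 23 IBM arrays, with 1 point for each array. Pearson's r was 0.902 for plasma cell, 0.614 for B cell and 0.737 for T cell genes as deposited, and with quantile normalization 0.901, 0.272 and 0.607.

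The comparison of PM with NORM asks the same of PM muscle. IGLV1-44 was 34-fold higher in PM (5.09 ± 0.80, n = 6 and 11), IGKC 19.8-fold (4.31 ± 0.86) and IGLC1 17.4-fold (4.12 ± 0.81), each above every NORM array in 5 of 6 PM arrays. PSMB8, at the floor in all 11 NORM arrays, was at least 32.9-fold higher and MYH3 29.5-fold higher (4.88 ± 0.62), both above every NORM array in 6 of 6. HLA-DQA1, an MHC class II chain, rose 18.9-fold (4.24 ± 0.80). HBB, the beta chain of adult haemoglobin, fell 3.62-fold (−1.86 ± 0.42) and was below every NORM array in 5 of 6 PM arrays. Without PM replicate 4 the same probe set of HBB fell 2.12-fold (−1.08 ± 0.29, adjusted p = 0.0162).

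Of the 11 immunoglobulin genes 5 were called higher and 0 lower (9 higher, adjusted over the list alone). Camera gave an adjusted p of 3.53e-06, and adjusted p = 0.194 with an estimated correlation. Of all 53 immunoglobulin probe sets 26 were called higher. The score was 2.44 higher in PM (exact permutation test, adjusted p = 0.00609), with 4 of 6 PM arrays above every NORM array and 1 below every NORM array. Of the 14 plasma cell genes 5 were called higher and 0 lower (9 higher, adjusted over the list alone): JCHAIN 12.5-fold (3.65 ± 0.82), FKBP11 8.35-fold (3.06 ± 0.47), PIM2 3.92-fold (1.97 ± 0.41), SEL1L3 2.80-fold (1.49 ± 0.47) and SSR4 2.32-fold (1.22 ± 0.29). The other 9 had log2 fold changes from −0.46 (TENT5C) to 1.58 (ITM2C), and with quantile normalization XBP1 was called higher (0.63 ± 0.20) and TENT5C lower (−0.72 ± 0.24). Camera gave an adjusted p of 0.000491 for the list, and adjusted p = 0.301 with an estimated correlation. The plasma cell score was 1.27 higher (exact permutation test, adjusted p = 0.00315), above every NORM array in 5 of 6 PM arrays.

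Of the 6 B cell genes CD79A was called higher (2.10-fold, 1.07 ± 0.35) and 0 lower (1 higher, adjusted over the list alone). MS4A1 had a log2 fold change of 0.08 ± 0.41 and CD22 of 0.62 ± 0.38, neither called. The B cell median was −0.0035, its mean was 0.18, and camera placed it below other genes without a call (adjusted p = 0.607). The score differed by 0.18 (exact permutation test, adjusted p = 0.531), by 0.37 without the arrays with a GAPDH ratio over 3 (adjusted p = 0.148) and by −0.06 with quantile normalization (adjusted p = 0.709).

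Of 12 T cell genes 5 rose, with CD4 5.95-fold higher (2.57 ± 0.57) and TRBC1 4.44-fold higher (2.15 ± 0.48). Of 14 cytotoxic genes 7 rose, with CD8A 4.59-fold higher (2.20 ± 0.48) and GZMA 3.39-fold higher (1.76 ± 0.39). Of 18 macrophage genes 15 rose, with AIF1 11-fold higher (3.46 ± 0.59) and CD163 7.09-fold higher (2.83 ± 0.40). The camera test had adjusted p-values of 1.39e-05, 1.22e-06 and 7.85e-16. The calls were lost with adjusted p = 0.23, adjusted p = 0.194 and adjusted p = 0.0935 with an estimated correlation. Each of the 3 scores was above every NORM array in 5 of 6 PM arrays. In the remaining array, PM replicate 6, the T cell and cytotoxic scores were below every NORM array.

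Of 15 MHC class I genes 12 rose, with HLA-B 4.56-fold higher (2.19 ± 0.22), and of 13 MHC class II genes 12 rose, with CD74 4.94-fold higher (2.31 ± 0.42). Camera gave adjusted p = 2.34e-16 and 1.86e-10, and adjusted p = 0.0724 and adjusted p = 0.0935 with an estimated correlation. Of 23 type I interferon genes 11 rose, with ISG15 7.51-fold higher (2.91 ± 0.42) and IFI35 3.52-fold higher (1.82 ± 0.34; camera adjusted p = 6.63e-09, adjusted p = 0.194 with an estimated correlation). Of 16 interferon gamma and chemokine genes 12 rose, with CCL2 9.06-fold higher (3.18 ± 0.49) and GBP2 5.66-fold higher (2.50 ± 0.39; camera adjusted p = 2.16e-14, adjusted p = 0.0935 with an estimated correlation). Of 15 complement genes 10 rose, with C3 4.01-fold higher (2.01 ± 0.36; camera adjusted p = 1.22e-06, adjusted p = 0.194 with an estimated correlation). Of 9 B cell survival genes 2 rose, with TNFSF13 5.38-fold higher (2.43 ± 0.49; camera adjusted p = 0.0263, adjusted p = 0.406 with an estimated correlation).

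Of 13 regeneration genes 7 rose, with GADD45A 9.59-fold higher (3.26 ± 0.41) and CHRNA1, an acetylcholine receptor subunit, 8.93-fold higher (3.16 ± 0.40), both above every NORM array in 6 of 6 PM arrays. The camera test had adjusted p = 7.11e-08, and adjusted p = 0.0935 with an estimated correlation. Of 29 myofibre genes 0 were called by limma, PVALB had 1.82 ± 0.69 and CASQ1 −0.42 ± 0.18, and the list median was −0.27 (camera adjusted p = 2.54e-10, adjusted p = 0.0627 with an estimated correlation). The fast fibre (median −0.36) and slow fibre (median −0.25) lists also had 0 calls, with MYL2 at −0.22 ± 0.11. Their camera adjusted p was 0.000147 and 0.000331, and they had adjusted p = 0.194 and adjusted p = 0.156 with an estimated correlation. With quantile normalization camera called none of these 3 lists (adjusted p = 0.0866, 0.333 and 0.382).

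Of 16 glycolysis genes 2 fell, with ENO3 1.56-fold lower (−0.64 ± 0.19; camera adjusted p = 5.51e-07, adjusted p = 0.0935 with an estimated correlation). Of 27 oxidative phosphorylation genes 0 were called, with UQCRB at −0.46 ± 0.17 and COX6A2 at −0.44 ± 0.17, and 7 were called lower with quantile normalization. The list median was −0.18 (camera adjusted p = 6.15e-08, adjusted p = 0.23 with an estimated correlation). Of 19 fatty acid oxidation genes 0 were called and PPARGC1A had −0.69 ± 0.30. That median was 0.03 and the mean was −0.14, and camera called the list lower than other genes (adjusted p = 0.00242, adjusted p = 0.339 with an estimated correlation). With quantile normalization 4 of these genes were called lower, PPARGC1A among them (−0.95 ± 0.26, adjusted p = 0.0092), and the score difference was −0.38 (exact permutation test, adjusted p = 0.0201).

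Of 22 extracellular matrix genes 5 rose, with TIMP1 5.47-fold higher (2.45 ± 0.31; camera adjusted p = 1.22e-05, adjusted p = 0.339 with an estimated correlation). Of 14 endothelial genes 5 rose, with VCAM1, an adhesion molecule for leukocytes, 6.17-fold higher (2.63 ± 0.46; camera adjusted p = 0.00632, adjusted p = 0.406 with an estimated correlation). Of 13 immediate early genes 5 rose, with MYC 5.37-fold higher (2.42 ± 0.48; camera adjusted p = 0.000891, adjusted p = 0.288 with an estimated correlation). Of 8 metallothionein genes 6 rose, with MT2A 2.95-fold higher (1.56 ± 0.25; camera adjusted p = 9.83e-07, adjusted p = 0.0935 with an estimated correlation). Of 18 endoplasmic reticulum stress genes 5 rose, with SDF2L1 2.82-fold higher (1.49 ± 0.33; camera adjusted p = 0.0426, adjusted p = 0.623 with an estimated correlation). Of 9 cell cycle genes 2 rose, with MCM5, a replication helicase subunit, 5.11-fold higher (2.35 ± 0.47; camera adjusted p = 0.0434, adjusted p = 0.431 with an estimated correlation and 0.104 with quantile normalization). Of 17 genes for proteins described in IBM fibres 4 rose, with CST3 3.20-fold higher (1.68 ± 0.28) and UCHL1 2.52-fold higher (1.33 ± 0.32), and camera did not call the list (adjusted p = 0.241). With quantile normalization camera called it higher (adjusted p = 0.0382), but not with an estimated correlation (adjusted p = 0.187).

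Of 3 erythrocyte genes 2 fell, HBB and HBD, and 0 rose. The list median was −1.33 (camera adjusted p = 6.85e-05, adjusted p = 0.0627 with an estimated correlation). The erythrocyte score differed from NORM by −1.18 (exact permutation test, adjusted p = 0.00315) and was below every NORM array in 4 of 6 PM arrays. Lists not called by camera had medians of 0.76 for dendritic cell genes (2 of 8 higher) and 0.27 for neutrophil and mast cell genes (0 of 8). They had medians of 0.20 for lysosome and autophagy genes (4 of 17 higher), 0.16 for adipocyte genes (0 of 9), 0.03 for keratinocyte genes (0 of 4) and 0.06 for ribosomal genes (1 of 20). Camera placed the neutrophil and mast cell, adipocyte, keratinocyte and ribosomal lists below other genes without a call (adjusted p = 0.882, 0.61, 0.582 and 0.515). AQP4 was 3.62-fold lower (−1.86 ± 0.41) and below every NORM array in 6 of 6 PM arrays. SLC7A2 was 3.98-fold lower, MASP1 3.10-fold and G0S2, an inhibitor of lipolysis, 2.90-fold.

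In all, limma called 763 genes between PM and NORM, 724 higher and 39 lower, with a median log2 fold change of all probe sets of 0.19 (−0.06 with quantile normalization). With that scaling 895 genes were higher and 521 lower, so the share of higher calls went from 94.9% to 63.2%. Of the calls as deposited, 683 higher and 38 lower genes were also called with quantile normalization, and 0 in the opposite direction. The count depended on single arrays: it was 409 without PM replicate 1 and 1287 without PM replicate 6, the array with a GAPDH ratio of 6.603. The count of lower genes was 18, 24 and 22 without PM replicates 2, 3 and 5, and 25 without NORM replicate 1 or 6. Calls were lost for CD79A with any of 15 arrays left out (0.90 to 1.10), for SEL1L3 with any of 9 (1.25 to 1.52), for SLC7A2 with any of 12 (−2.06 to −1.81), for ENO3 with PM replicates 1 and 4 and NORM replicates 9 and 11 (−0.64 to −0.61) and for MASP1 with PM replicate 2 (−1.38). The camera call was lost for endothelial genes without PM replicate 6 (0.74), for endoplasmic reticulum stress genes without PM replicate 4 or 6 or NORM replicate 9 or 10 (0.43 to 0.76) and for cell cycle genes with any of 7 arrays left out (0.35 to 0.76). Without PM replicate 6, POU2AF1 (1.69), XBP1 (1.12), PVALB (2.50), COX6A2 (−0.54) and MYL2 (−0.34) were called. PVALB was also called without NORM replicate 6 (2.27), ITM2C without PM replicate 4 (2.06) and UQCRB without IBM replicate 23 (−0.46) or NORM replicate 11 (−0.52). The lysosome and autophagy list was called without PM replicate 5 (0.31), but not with an estimated correlation (adjusted p = 0.621).

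The fold changes of IBM and PM against NORM were correlated across 8555 genes with r = 0.907; genes are not independent replicates. Because both comparisons share the NORM arrays, simulated groups without any difference gave a mean r of 0.476, and NORM arrays divided between the comparisons gave 0.788. The covariance was 0.298, against 0.0248 simulated. Genes called higher in both numbered 686, against 140 for independent lists. Genes called lower in both numbered 24, against 0.615 for independent lists, and 0 were called in opposite directions. The simulations gave a mean of 3.51 genes called in both comparisons, with no separate value for each direction. With the NORM arrays divided, 332 genes were called higher and 2.58 lower in both on average. That division leaves fewer controls in each comparison and so fewer calls, and its counts are not what chance would give. The 710 calls in the same direction became 387 without PM replicate 1 and 1139 without PM replicate 6.

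The comparison of IBM with PM asks whether the diseases differ. Limma called 0 genes. Of the 8555 genes tested, 161 had an unadjusted p under 0.05, a smaller share than the 0.05 that unchanged genes would give on average. The smallest adjusted p was 0.0896, for HBB. HBB was 3.27-fold higher in IBM (1.71 ± 0.38, n = 23 and 6) and HBD, the delta chain of haemoglobin, 2.94-fold higher (1.55 ± 0.37), neither past the threshold. PAMR1 (1.87 ± 0.50), KIR2DL5A (1.16 ± 0.34) and PRDM11 (1.06 ± 0.31) had the next smallest p among genes with higher values in IBM. TRIB3, a stress-induced pseudokinase (−1.21 ± 0.31), MT1HL1 (−1.10 ± 0.32), MT1H (−0.89 ± 0.27), GDF15 (−1.13 ± 0.37) and NPIPA1 (−0.67 ± 0.20) had the smallest p among genes with lower values. HBB was called without IBM replicate 11 (adjusted p = 0.041) or 20 (0.042) and without PM replicate 2 (0.0259) or 3 (0.0109), and TRIB3 without PM replicate 2 (0.0259). Without PM replicate 4 the difference of HBB was 0.94 ± 0.27 on the same probe set.

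Erythrocyte genes had a median log2 difference of 1.55 (camera adjusted p = 1.55e-10) and metallothionein genes of −0.65 (camera adjusted p = 1.85e-11). Both calls held with an estimated correlation (adjusted p = 0.000147 and adjusted p = 0.0217). Adjusted over the list alone, 2 of 3 erythrocyte genes were higher in IBM and 6 of 8 metallothionein genes lower. The erythrocyte score was 1.24 higher in IBM (permutation test, exact, adjusted p = 0.00695), and 19 of 23 IBM arrays lay above every PM array. Without PM replicate 4 that difference was 0.88 and not called (adjusted p = 0.0954), nor was it called with array medians subtracted (1.23, adjusted p = 0.0543) or without a filter on dim probe sets (0.79, adjusted p = 0.139). The metallothionein score differed by −0.53 without a call (exact permutation test, adjusted p = 0.213).

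**Figure D5:**
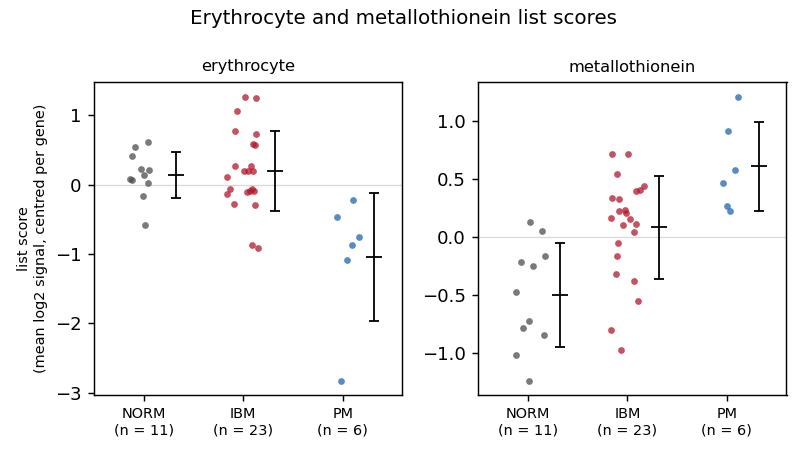
Erythrocyte and metallothionein list scores (vertical axis, mean log2 signal centred per gene) in each array of NORM (n = 11), IBM (n = 23) and PM (n = 6) on the horizontal axis; points are arrays, and the line and bar are the mean ± 1 SD. The erythrocyte score was 1.24 higher in IBM than in PM, and all 6 PM arrays lay above every NORM array in the metallothionein score.

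Immunoglobulin and plasma cell genes were not shown to differ between the diseases. The immunoglobulin list median was 0.29 (camera adjusted p = 0.0937), with IGHM at 1.56 ± 0.81, and of 53 immunoglobulin probe sets 0 were called. That median was −0.26 without PM replicate 6. The list was called without PM replicate 3 (0.52) or 5 (0.36) and without IBM replicate 3, 9, 14, 16, 17 or 18 (0.29 to 0.38), though in none of these with an estimated correlation (adjusted p = 0.696 to 0.999). The plasma cell median was 0.04 (camera adjusted p = 0.882), with SSR4 at −0.28 ± 0.26. Camera called the B cell list higher in IBM than other genes (median 0.23, adjusted p = 0.0234), with BLK at 0.60 ± 0.29, but with adjusted p = 0.79 with an estimated correlation. Without the low-scaled arrays the B cell median was 0.15 and without the arrays with a GAPDH ratio over 3, with quantile normalization, 0.11, and both calls were lost. The B cell call was also lost without PM replicate 1 (0.37) or 4 (0.30) or IBM replicate 23 (0.23).

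Further lists called higher in IBM by camera were neutrophil and mast cell genes (median 0.30, CPA3 at 0.69 ± 0.41, adjusted p = 0.0234), extracellular matrix genes (0.22, MMP2 at 0.86 ± 0.39, adjusted p = 0.0133) and adipocyte genes (0.48, CFD at 1.03 ± 0.38, adjusted p = 0.0234). They had adjusted p = 0.804, adjusted p = 0.98 and adjusted p = 0.804 with an estimated correlation. Lists called lower were immediate early genes (−0.35, MYC at −1.18 ± 0.43, adjusted p = 8.1e-05) and ribosomal genes (−0.10, RPL19 at −0.21 ± 0.12, adjusted p = 0.00189). Lysosome and autophagy genes (−0.20, MAP1LC3B at −0.38 ± 0.21, adjusted p = 0.00822), endothelial genes (−0.24, CLDN5 at −0.73 ± 0.33, adjusted p = 0.0234) and regeneration genes (−0.26, CHRND at −1.09 ± 0.51, adjusted p = 0.0281) were also called lower. These 5 had adjusted p = 0.76, adjusted p = 0.804, adjusted p = 0.87, adjusted p = 0.923 and adjusted p = 0.87 with an estimated correlation. With quantile normalization the regeneration list was not called (adjusted p = 0.0574). Without PM replicate 4 the calls of extracellular matrix (0.0023), neutrophil and mast cell (0.18), adipocyte (0.54) and regeneration genes (0.08) were lost. Further omissions that ended a call were PM replicates 2 and 5 for adipocyte genes (0.29 and 0.43), PM replicate 1 and IBM replicates 6 and 23 for neutrophil and mast cell genes (0.21 to 0.40) and PM replicates 1, 2 and 6 for endothelial genes (−0.26 to −0.04). PM replicate 6 did so for ribosomal genes (−0.07), and PM replicate 2 and IBM replicates 4, 7 and 16 for regeneration genes (−0.30 to −0.08). The number of lists called was 6 without PM replicate 4 and 20 without PM replicate 6, against 11.

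The remaining lists were not called between IBM and PM with all arrays. Their medians were 0.02 for T cell genes (CD5 at 0.42 ± 0.46), −0.08 for cytotoxic genes (NKG7 at −1.07 ± 0.66), −0.00094 for macrophage genes (LYZ at 0.58 ± 0.58) and −0.03 for dendritic cell genes. They were −0.03 for MHC class I genes (TAPBP at −0.42 ± 0.39), 0.06 for MHC class II genes (HLA-DOB at −0.56 ± 0.41), −0.15 for type I interferon genes (ISG15 at −0.60 ± 0.38) and −0.09 for interferon gamma and chemokine genes (CXCL13 at −1.44 ± 0.53). B cell survival genes had 0.02, complement genes 0.12, myofibre genes 0.0019 (MYBPC1 at 0.16 ± 0.13), fast fibre genes 0.03 and slow fibre genes −0.03. Oxidative phosphorylation genes had 0.09 (UQCRB at 0.27 ± 0.15), fatty acid oxidation genes −0.03 and glycolysis genes 0.0036. Genes for proteins described in IBM fibres had −0.03 (MAPT at 0.37 ± 0.22), endoplasmic reticulum stress genes −0.04, keratinocyte genes 0.27 and cell cycle genes −0.11. The median and the mean had opposite signs for macrophage, dendritic cell, MHC class II, B cell survival, myofibre and glycolysis genes. Without PM replicate 6, the array with a GAPDH ratio of 6.603, camera called 8 immune lists lower in IBM: T cell (−0.48), cytotoxic (−0.51), macrophage (−0.46), MHC class I (−0.41), MHC class II (−0.64), type I interferon (−0.32), interferon gamma and chemokine (−0.52) and B cell survival genes (−0.38). With an estimated correlation these had adjusted p = 0.565 to 0.704, so none was called. Camera also called oxidative phosphorylation (0.04), myofibre (0.04) and slow fibre genes (0.10) higher in IBM without that array. Further calls were gained for keratinocyte genes with any of 7 arrays left out (0.25 to 0.33), for oxidative phosphorylation genes with any of 4 others (0.08 to 0.12) and for type I interferon genes with any of 4 others (−0.21 to −0.15). Cytotoxic (−0.28) and interferon gamma and chemokine genes (−0.22) were called without PM replicate 2 and myofibre genes (−0.05) without PM replicate 1. Of all 37 list calls gained between IBM and PM with 1 array left out, 0 held with an estimated correlation (adjusted p = 0.565 to 0.999). A p that missed the threshold with 6 PM arrays does not show that the groups were alike.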

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

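Of the tests in this part, those of RNA degradation and of scaling were chosen after the erythrocyte result was seen, and that of alpha globin was written before its result.

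In PM, single arrays stood far from the other 5. Of 33 list scores and 87 named genes examined, 8 scores and 10 genes had a gap to the nearest array that was too large a part of the range (Dixon's critical ratio 0.625). Chance gives about 5 in 100 groups, and the items are not independent, since most pointed to the same arrays. PM replicate 6, which was low-scaled and had a GAPDH 3' to 5' ratio of 6.603, was lowest in the MHC class II (ratio 0.647), B cell survival (0.669), glycolysis (0.716), keratinocyte (0.627), ribosomal (0.643) and cell cycle (0.712) scores. It was also lowest in PSMB8 (0.649), CD4 (0.799), CD74 (0.66), TNFSF13 (0.675), CD5 (0.67), LYZ (0.785) and TAPBP (0.687), and highest in MYL2 (0.664). PM replicate 4 was lowest in the erythrocyte score (0.666), HBB (0.67) and HBD (0.76). PM replicate 1 was highest in the fatty acid oxidation score (0.701). The GAPDH ratio was above every NORM array in 6 IBM arrays and 1 PM array.

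The erythrocyte score was 1.24 higher in IBM than in PM, but this call was lost with array medians subtracted (1.23, exact permutation test, adjusted p = 0.0543) and without a filter on dim probe sets (0.79, adjusted p = 0.139, 6 genes). A filter at the 75th percentile left 2 genes, so the list was not tested there. Arrays with a GAPDH ratio over 3 as the whole cause of the PM difference from NORM are argued against. Without them that difference was −1.24 (exact permutation test, adjusted p = 0.00178). Scaling as the whole cause of that PM difference is argued against by −1.47 with quantile normalization (exact permutation test, adjusted p = 0.000762) and −1.46 with array medians subtracted (adjusted p = 0.001). Less blood in the PM specimens may account for it. The 6 alpha globin probe sets differed by −2.01 between PM (mean log2 14.3 ± 1.81 SD, n = 6) and NORM (16.31 ± 0.438, n = 11; exact permutation p = 0.000485), with 16.05 ± 0.719 in IBM (n = 23). They were outside the list test only because they carry several symbols. Alpha globin is a red cell transcript like HBB and HBD, so its fall repeats the pattern and does not decide the cause. Its difference without PM replicate 4 was not tested. Without PM replicate 4 the list difference from NORM was −0.824 (exact permutation test, adjusted p = 0.00697), and neither how the specimens were taken nor a difference between the diseases themselves was tested.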

How the results depend on the processing

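The settings with low-scaled arrays or GAPDH ratios over 3 were chosen after the data were seen, and the cause of the changes below was not tested unless the setting itself states it. Each count is set against 1795 genes called (1660 higher, 135 lower) in IBM against NORM, 763 (724, 39) in PM against NORM, 0 in IBM against PM, 710 calls shared in direction, 22, 25 and 11 lists called by camera, and 1 list score called between IBM and PM. Counts not named stayed within 1.5 times these, and no named gene that was called against NORM changed direction except CASQ2. Probe sets near the floor limit what small changes can show, and no paired analysis was possible because the labels pair no samples.

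Quantile normalization gave 1083 lower genes in IBM, 1416 called and 521 lower in PM, and 1211 shared calls. Subtraction of array medians gave 1257 lower genes in IBM, 1353 called and 496 lower in PM, 1166 shared calls and 0 list scores between IBM and PM. Without a filter there were 25 lower genes in PM, 0 list scores, and 1 gene called, lower, between IBM and PM (FBXL8, −0.622, adjusted p = 0.00328). The filter at the 75th percentile gave 0 list scores between IBM and PM, but the erythrocyte list had 2 genes left and was not tested there. That filter gave a called immunoglobulin median of 0.329 between IBM and PM (0.286, not called, otherwise), with adjusted p = 0.991 with an estimated correlation. The GAPDH covariate gave 1095 higher genes in PM and a called immunoglobulin median of 0.332, with adjusted p = 0.948 with an estimated correlation. Array weights gave 547 lower genes in IBM, 1883 called (1553 higher, 330 lower) in PM, 1616 shared calls and 17 lists between IBM and PM.

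A block for low-scaled arrays gave 357 lower genes in IBM and 107 in PM, and their omission 262 and 88. Within the 7 low-scaled arrays, 28 genes (25 higher, 3 lower) and 10 lists were called in IBM. The plasma cell median of 0.28 was not called, and signs turned, without a call, for fast fibre (0.102) and CASQ2 (−0.199). This fit had fewer samples, and only 4449 genes passed the signal filter, against 8555 with all arrays. Genes dim in NORM could be removed by that filter, so these counts are not comparable with those from all arrays. Without GAPDH ratios over 3 there were 1263 genes called and 1232 higher in PM, and 1129 shared calls. Quantile normalization without low-scaled arrays gave 1068 lower genes in IBM, 1601 called and 688 lower in PM, 1372 shared calls and 18 lists between IBM and PM. Quantile normalization without GAPDH ratios over 3 gave 1207 lower genes in IBM, 1673 called and 691 lower in PM, 1441 shared calls, and 5 of 10 correlations with the immunoglobulin score called.

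Between IBM and PM, the B cell median (0.235) lost its call without a filter (0.157), with weights (0.0662), without low-scaled arrays (0.15; 0.201 with quantile normalization), and without GAPDH ratios over 3 under quantile normalization (0.107). Lists not called otherwise were called by camera in the other direction, for slow fibre with weights (0.0689), without low-scaled arrays (0.0937) and without GAPDH ratios over 3 (0.0718), for fatty acid oxidation with weights (0.0182) and for myofibre without GAPDH ratios over 3 (higher than other genes, median −0.00192). With quantile normalization and no low-scaled arrays this held for fast fibre (−0.133) and glycolysis (−0.0782). An estimated correlation, tried after the data were seen, ended all 45 list calls gained between IBM and PM in these settings (adjusted p = 0.553 to 0.991). With all arrays as deposited it ended the calls of the immunoglobulin and plasma cell lists in IBM (1.84 and 1.09) and PM (1.87 and 1.26) and of the B cell list between IBM and PM (0.235), and left 1, 0 and 2 lists called. Fry called the B cell list in IBM (0.458) and 1 list between IBM and PM, not the B cell list (0.235). It turned the ribosomal direction in IBM without a call (median −0.0612, fry adjusted p = 0.964).

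With each array left out in turn, IBM against NORM gave 1440 to 2156 genes. PM against NORM gave 409 (without PM replicate 1) to 1287 (without PM replicate 6), 381 to 1255 higher and 18 (without PM replicate 2) to 46 lower. IBM against PM gave 0 to 2 genes, 0 to 1 in each direction, with the 2 without PM replicate 2. The 710 shared calls ran from 387 to 1139, the lists between IBM and PM from 6 (without PM replicate 4) to 20 (without PM replicate 6) and the list scores from 0 (without PM replicate 4) to 1. Between IBM and PM, the immunoglobulin median ran from −0.265 to 0.521, B cell from 0.0685 to 0.369, T cell from −0.482 to 0.271, myofibre from −0.0488 to 0.0485 and slow fibre from −0.0903 to 0.104. Without PM replicate 6 camera called T cell (−0.482) and slow fibre genes (0.104) in the other direction. It called myofibre genes higher than other genes without PM replicate 6 (0.0393) and lower without PM replicate 1 (−0.0488), against a median of 0.00194 that was not called. An estimated correlation, chosen after the data were seen, ended all 37 list calls gained between IBM and PM with 1 array left out.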

Other observations

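The tests of splits, scaling, RNA degradation, the difference between correlations and the difference between scores in this part were chosen after the results were seen. Those of dim probe sets and of the amount of infiltrate were written before their results.

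Several gene groups had higher scores in disease although camera did not call their lists against other genes with the arrays as deposited. In IBM the endothelial score was 0.61 higher than in NORM (permutation test, adjusted p = 0.00566), with VCAM1 5.24-fold higher (2.39 ± 0.33) and CLDN5, a tight junction protein of vessels, 1.99-fold higher (1.00 ± 0.26). The score of genes for proteins described in IBM fibres was 0.47 higher in IBM (permutation test, adjusted p = 0.00315) and 0.49 higher in PM (exact permutation test, adjusted p = 0.0216). UCHL1 was 2.37-fold higher in IBM. The cell cycle score was 0.63 higher in IBM (permutation test, adjusted p = 0.00334), with MCM5 3.5-fold higher (1.81 ± 0.34; 1.59 with quantile normalization). The immediate early score was 0.66 higher in IBM (permutation test, adjusted p = 0.00825), with MYC 2.37-fold higher (1.25 ± 0.35). The dendritic cell score was 0.80 higher in IBM (permutation test, adjusted p = 0.00334), that of neutrophil and mast cells 0.65 higher (adjusted p = 0.0193) and the adipocyte score 0.68 higher (adjusted p = 0.0364). With quantile normalization the last 2 differences were 0.40 and 0.44 and not called (adjusted p = 0.0529 and 0.111). Those of the endothelial and cell cycle scores shrank to 0.34 each (adjusted p = 0.00136 and 0.00142) and that of the immediate early score to 0.40 (adjusted p = 0.014). The lysosome and autophagy score was 0.58 higher in PM (exact permutation test, adjusted p = 0.0455; 0.32 with quantile normalization) and 0.39 higher in IBM without a call (permutation test, adjusted p = 0.0606; 0.15 with quantile normalization). Without the arrays with a GAPDH ratio over 3 that IBM difference was 0.45 and called (adjusted p = 0.0439).

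Random splits of the arrays did not reach the counts of genes called against NORM. With 100 splits the smallest possible result is 1 in 100. Each split also mixes disease and NORM arrays in both groups, which widens the spread within groups and makes few calls likely. Scaling or RNA quality that moved with the group was not tested by these splits. Of 100 splits of the 34 IBM and NORM arrays into groups of these sizes, 1, the real split with 1795 genes, reached that count, and the highest of the others was 0. Of 100 splits of the 17 PM and NORM arrays, 1, the real split with 763 genes, reached it, and the highest of the others was 2. For IBM and PM the real count was 0, which all 100 splits reach by necessity, so the splits say nothing about chance there. Of the other splits 6 called any gene, and 1 of them called 508. The cause of these calls was not identified. The smaller group of the split with 508 calls held 3 of the 4 low-scaled arrays, and 1 array there had a GAPDH ratio over 3. Of 3 splits with at least 3 low-scaled arrays in the smaller group 1 called any gene, and a split with 1 such array also called genes. With only 3 such splits, it cannot be told whether the low-scaled arrays account for the calls.

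More genes were called higher than lower against NORM. With the GAPDH ratio as a covariate 93.7% of calls in IBM and 95.9% in PM were higher. The median GAPDH ratio differed little between groups (0.8758 in IBM, 0.875 in PM and 0.8418 in NORM). That covariate could therefore take out little of a difference in RNA quality shared by a whole group. The 3' to 5' ratio of the control transcript ACTB was not used as a covariate. It ran from 0.6865 to 5.416 in IBM, 0.959 to 3.682 in PM and 0.4502 to 1.373 in NORM. RNA degradation was thus not excluded as a cause. For all calls, the scaling between arrays cannot be told apart from a real rise. With a block for low-scaled arrays 81.5% of calls in IBM and 89.9% in PM were higher, and without these arrays 84.2% and 91%. Quantile normalization left 56.9% of calls higher in IBM and 63.2% in PM, but it gives all arrays 1 distribution, which moves the balance towards 50% with or without such a rise. Among calls of at least 2-fold it left 90.3% and 86.6% higher, which argues against scaling as the whole cause there.

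Immunoglobulin genes rose more than B cell markers in IBM: the difference between the 2 scores was 2.32 larger than in NORM as deposited and 2.38 larger with quantile normalization (permutation p = 1e-05 for both, the smallest possible). Given the T cell score, the partial correlation of the immunoglobulin and plasma cell scores was 0.84 with quantile normalization (permutation p = 1e-05) and 0.784 as deposited (permutation p = 6e-05). These scores thus varied together beyond the T cell score. Both hold transcripts of antibody-secreting cells, so this cannot decide whether the amount of infiltrate alone accounts for the gap to B cell markers. The partial correlation of the immunoglobulin score with the B cell score, given the T cell score, was 0.362 with quantile normalization (permutation p = 0.0898). The correlation with the plasma cell score exceeded that with the B cell score by 0.629 with quantile normalization (95% bootstrap interval 0.227 to 1.03) and by 0.288 as deposited (0.0577 to 0.651), but in the 20 IBM arrays with a GAPDH ratio of at most 3 by 0.362 (0.0773 to 0.752) and 0.164 (−0.00699 to 0.449), so whether plasma cells more than B cells were the source stays open. Dim probe sets that hide B cell changes were not excluded either: 10 equally dim T cell and cytotoxic genes had a median log2 fold change of 1.29, with 6 of them above every B cell gene, but the highest of the 6 B cell genes had 1.23. The plasma cell list also holds genes of other secretory cells, and no cell counts were available.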
